A study of Caenorhabditis elegans with 4 samples.

How the data were processed

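The samples were whole hermaphrodites of Bristol N2, the wild-type laboratory strain of the nematode Caenorhabditis elegans. Per the labels' protocols, worms 3 days old were kept for 1 day on plates of modified nematode growth medium covered with Escherichia coli OP50, the standard laboratory food bacterium, or with OP50 and nisin, and were 4 days old when collected. Nisin is an antimicrobial peptide of the lantibiotic class made by Lactococcus lactis and used as a food preservative. About 200 worms were collected per group, total RNA was isolated with a lipid tissue kit, poly(A) RNA was selected with magnetic beads and the libraries were made with a kit that keeps the strand of the RNA, per the labels' protocols. Each group had 2 libraries, so 4 libraries were analysed in all. The labels do not say that the 2 libraries of a group came from separate cultures. Every p-value below that rests on spread between libraries thus measures only the spread between these samples, which may be technical. P-values of list tests with a preset correlation, and of permutations across genes, take genes as their units and do not measure spread between libraries.

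The deposited values are counts per gene, 1 table per library; they are whole numbers with a different total in each library, so they were treated as counts that the authors had not scaled. Per the submitters' processing notes, the tools included Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.10a and featureCounts 2.0.1, and the genome builds named were ce11 and WBcel235. Their order, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Every table had the same 46258 gene rows, all of whose WormBase identifiers and coordinates matched the Ensembl release 115 annotation of WBcel235. Of these, 19973 were protein-coding and 15363 were piRNA rows, 0 rows lay on the mitochondrial genome and 0 were ribosomal RNA rows. A count of 0 stood in all 4 libraries for 22200 rows. The 2128 rows with no gene name in the tables took their name from the reference table or their sequence name. Of 10 single-exon rows lying inside an exon of an abundant gene on the same strand, 0 held counts, and of 10 such rows on the opposite strand 9 held counts, so the counting used strand. Genes that overlap on the same strand and genes with a near-identical copy can still lose or exchange reads and are named below as uncertain.

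Total counts were 40271356 and 36012077 in control replicates 1 and 2, and 42517280 and 46307497 in nisin replicates 1 and 2. At these totals 3 counts, taken as the upper limit that a count of 0 allows, correspond to 0.0648 to 0.0833 CPM (counts scaled to a common library total). The 95% intervals of shares of counts are Wilson intervals. These intervals and limits cover counting error only, because reads made by PCR without molecular identifiers are not independent molecules.

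Groups were compared in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, on the deposited counts of all 4 libraries with no covariate, after trimmed-mean scaling and edgeR's default filter on low counts given the groups, which kept 16487 genes. P-values were adjusted by Benjamini and Hochberg's method and the threshold was 0.05. Fold changes are nisin over control. The standard error of a log2 fold change is the size of the change divided by the square root of its F statistic, and its 95% interval uses the degrees of freedom of that test. This replaced a standard error from the fitted coefficients after both had been seen, so that the interval follows the test that gives the p-value. CPM values use the same scaling.

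Before the data were examined, 49 gene lists, 16 single genes, the test, the rule for naming genes and the alternatives were fixed. Of the lists, 48 had rows and were tested; the list of mitochondrially encoded genes had none. Over all lists 21 names matched no row. Lists were tested with camera in limma 3.58.1 on voom log2 CPM, with the preset correlation between genes of 0.01 and at least 5 tested members, adjusted over the 48 lists; camera was repeated with an estimated correlation, and fry tested whether a list moved by itself. The naming rule took, in each direction, the 10 genes with the largest change among those with an adjusted p under 0.05, a mean of at least 5 CPM and both nisin libraries on one side of both control libraries. With fewer than 5 such genes in a direction it took the 5 with the smallest unadjusted p at a mean of at least 5 CPM, named as not passing. It added up to 4 members with the smallest p from each list past the list test or with at least 3 members past the gene test, and the 16 single genes. Any gene outside this rule is said to have been chosen after its values were seen.

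The tests were checked on simulated data drawn from the libraries' own means, totals and gene-wise dispersions for nisin against control, over 16487 genes with 200 changed. Of 67 genes changed 1.5-fold the edgeR test recovered 3 (4.48%), of 67 changed 2-fold it recovered 26 (38.8%), and of 66 changed 4-fold it recovered 66 (100%), with 6 false calls. With no change simulated it made 0 calls. Over 16270 simulated genes, camera recovered 5 of 5 lists shifted 1.3-fold with the preset correlation and 0 of 5 with an estimated one, and called 1 of 15 unshifted lists. Simulated genes were drawn independently, with no shift shared by many genes between libraries of a group. In the data, estimated correlations between genes of a list ranged from -0.12 to 0.98. The rates of recovery and of false calls therefore need not carry over to the data. An exact permutation test of 2 libraries against 2 cannot go below p = 0.33 (two-sided), so no single value was tested that way.

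Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, library totals only, no filter, a mean count of at least 50, DESeq2 and limma-voom as tests, 2 variants of the edgeR fit, the replicate number as a block, leaving out each library in turn, and stricter thresholds. Leaving out mitochondrial and ribosomal RNA genes was not run because the tables hold 0 such rows. Tests of gene ontology (GO) terms that the deposited tables give each gene, with 10 to 500 tested members, as well as other splits of the libraries and a crossed pairing, were added after the data had been seen.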

Results

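Messenger RNA of whole worms was measured in 4 libraries, 2 from worms fed E. coli OP50 and 2 from worms fed OP50 with nisin for 1 day before collection at 4 days of age. The question, as the series states it, was which genes feeding nisin regulates. Between 36012077 and 46307497 counts fell on genes in each library, and 21050 to 21335 genes had at least 1 count. The 10 most abundant genes took 4.22% of the counts (95% interval 4.212 to 4.224) in control replicate 1, 4.1% (4.096 to 4.109) in control replicate 2, 3.93% (3.926 to 3.938) in nisin replicate 1 and 4.26% (4.253 to 4.265) in nisin replicate 2, so no small set of genes dominated a library. The most abundant were the translation elongation factor eef-1A.1 and the yolk protein genes vit-6, vit-2 and vit-5.

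Germline and somatic genes differed in opposite directions between libraries of the same group. Genes of oocytes and the eggshell were lower in control replicate 2 than in control replicate 1, with a median log2 gap of -0.70 over 29 genes, and higher in nisin replicate 2 than in nisin replicate 1, with a median gap of 0.43. Germ granule and meiosis genes had gaps of -0.64 and 0.41. Body wall muscle genes, pharyngeal muscle genes and pan-neuronal synaptic genes had gaps of the opposite sign, 0.62, 0.69 and 0.62 between the controls and -0.26, -0.37 and -0.38 between the nisin libraries. Each of these 10 gaps lay outside the middle 95% of 10000 random lists of the same size matched on mean expression. The gaps between groups were smaller for the same lists, with nisin minus control medians of -0.03 for oocyte and eggshell genes, -0.05 for germ granule and meiosis genes, 0.03 for body wall muscle genes, -0.0049 for pharyngeal muscle genes and 0.02 for synaptic genes.

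Yolk protein genes, whose proteins are made in the intestine, moved with the germline genes. The 6 vitellogenins took 2.14% of the counts in control replicate 1 (95% interval 2.137 to 2.146) and 2.04% in nisin replicate 2 (2.031 to 2.04), against 1.72% in control replicate 2 (1.715 to 1.724) and 1.57% in nisin replicate 1 (1.569 to 1.577). Across genes, log2 CPM correlated at 0.9817 between the 2 control libraries and at 0.9911 between the 2 nisin libraries, while control replicate 1 correlated at 0.9944 with nisin replicate 2 and control replicate 2 at 0.9938 with nisin replicate 1. The same-numbered libraries of the groups correlated at 0.9866 (replicates 1) and 0.9866 (replicates 2), below the value between the nisin libraries. These are correlations across genes, which are not independent replicates. The first principal component held 69.5% of the variance and separated the libraries within each group, and the second held 16.7% and separated nisin from control. None of the 4 pairs of libraries compared agreed within sampling noise, with chi-square per degree of freedom of 13.2 or more.

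**Figure D1:**
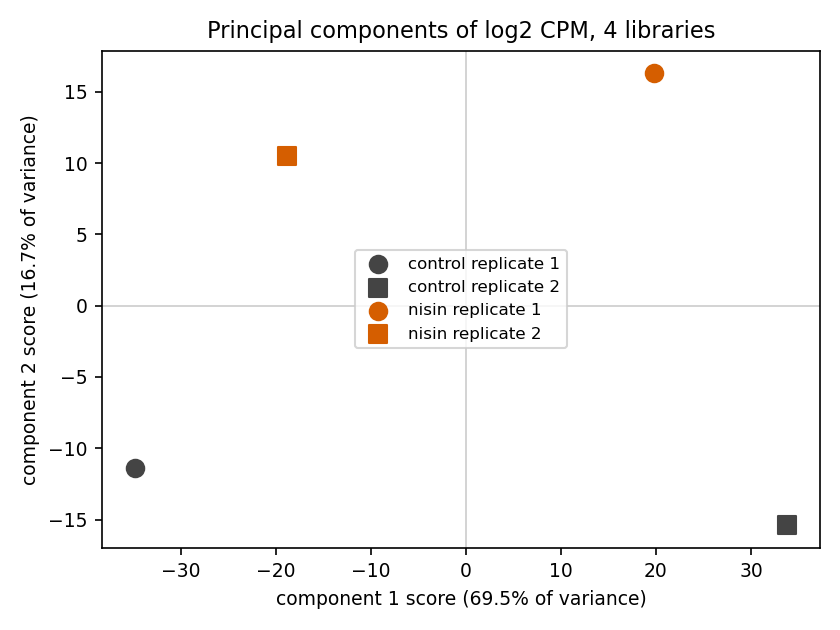
Scores of the 4 libraries on the first and second principal components of log2 CPM over the tested genes, with the share of variance on each axis; grey marks control, orange marks nisin, circles replicate 1 and squares replicate 2. On component 1 the controls lie at -34.8 and 33.8 and the nisin libraries at 19.8 and -18.8; on component 2 the controls lie at -11.4 and -15.4 and the nisin libraries at 16.3 and 10.5.

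No gene passed the test between nisin-fed and control worms. Of 16487 genes, edgeR's quasi-likelihood test called 0 higher and 0 lower at an adjusted p under 0.05; 65 had an unadjusted p under 0.05 (42 higher, 23 lower), where chance alone would give 824. That count of 65 was 661 without control replicate 1, 502 without control replicate 2, 70 without nisin replicate 1 and 110 without nisin replicate 2. DESeq2 called 1 gene higher and 0 lower, and limma-voom called 0. The common biological coefficient of variation was 19.7%, and of 11019 genes with a mean of at least 5 CPM, 97.9% had a 95% interval of the fold change within 2-fold in both directions. Among those 11019 genes, 2 had a fitted change over 2-fold and 13 over 1.5-fold. Both nisin libraries lay on one side of both controls for 8.53% of them, where chance alone would give 33.3%. Genes are not independent draws, and the component that separated libraries within groups held 69.5% of the variance. Such gaps enter the spread that the gene test measures. These 2 shortfalls against chance therefore do not show that nisin changed no gene.

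Both genes with a mean of at least 5 CPM and a fitted change over 2-fold were higher in the nisin libraries. T22F3.11 (WBGene00020700), annotated with transmembrane transporter activity and lying on chromosome V from 3612158 to 3614553 (WBcel235, exonic counts as for all genes here), stood at 24.6 ± 10.6 CPM (SD, n = 2) with nisin and 5.90 ± 1.55 CPM (SD, n = 2) without, a log2 fold change of 2.06 (SE 0.36; 95% interval 1.25 to 2.88; edgeR adjusted p = 1). It was the 1 gene that DESeq2 called (log2 2.05, adjusted p = 2.82e-05). Its edgeR log2 value was 1.82 without control replicate 1 and 2.36 without control replicate 2. Over all left-out libraries in turn, the T22F3.11 value ran from 1.54 to 2.44. F46C5.1 (WBGene00009778), annotated to the membrane, lies on chromosome II from 8820153 to 8821190, opposite the noncoding row linc-72. It stood at 8.60 ± 2.13 CPM (SD, n = 2) against 3.37 ± 1.05 CPM (SD, n = 2), with a log2 fold change of 1.36 (SE 0.34, edgeR adjusted p = 1). Over all left-out libraries in turn, the F46C5.1 value ran from 1.07 to 1.71, the latter without control replicate 2.

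The other 8 genes named for a small unadjusted p did not pass either. On the higher side, sodh-1, an alcohol dehydrogenase gene, had a log2 fold change of 0.62 (SE 0.19) from 271 ± 54.6 to 415 ± 60.9 CPM (SD, n = 2 each). The noncoding RNA rncs-1, known to bind Dicer, had 0.61 (SE 0.22), and F43C11.7, annotated with defense response to Gram-positive bacteria, had 0.69 (SE 0.27). On the lower side, the inducible heat shock genes hsp-16.41, hsp-16.2 and hsp-70 had log2 fold changes of -0.51 (SE 0.21), -0.47 (SE 0.22) and -0.50 (SE 0.23). F40G9.6, annotated to the membrane, had -0.56 (SE 0.28), and F14B4.1, annotated with endocytosis, had -0.53 (SE 0.26). Both nisin libraries lay above both controls for the 5 higher genes and below both for the 5 lower genes. These genes were picked by their p among the 11019 genes with a mean of at least 5 CPM.

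**Figure D2:**
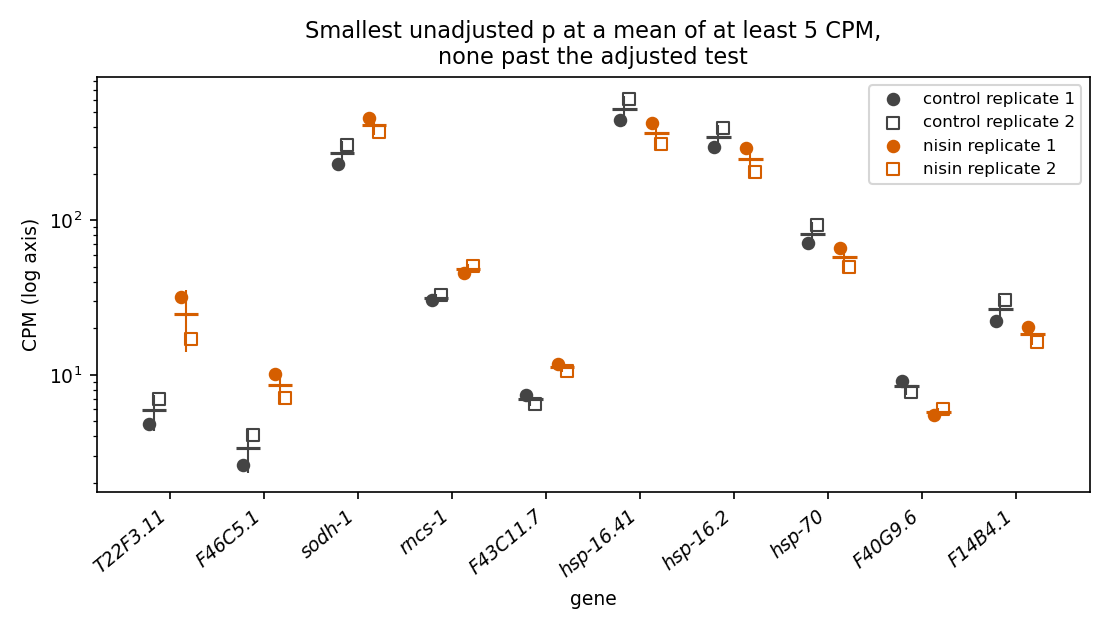
CPM per library on a log axis for the 5 genes with the smallest unadjusted p in each direction among those with a mean of at least 5 CPM; grey is control, orange is nisin, filled circles replicate 1, open squares replicate 2, horizontal lines group means and vertical lines 1 SD (n = 2). T22F3.11 stands at 4.80 and 6.995 CPM in the controls and 32.1 and 17.1 CPM in the nisin libraries; none of the 10 genes passed the adjusted test.

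As sets, lysozyme, intestinal protease and neuropeptide genes were among those that ranked higher in the nisin libraries than other genes did, and heat shock genes ranked lower. With the preset correlation, camera placed 14 of the 48 lists higher and 1 lower at an adjusted p under 0.05. With an estimated correlation 0 lists passed (smallest adjusted p = 0.756), and fry, also in limma, called 0 (smallest adjusted p = 0.58). In the simulation, whose genes were drawn independently, an estimated correlation recovered 0 of 5 shifted lists. A call lost with it thus does not by itself argue against a shift. How often the preset correlation calls unshifted lists of genes that move together was not simulated. Fry was not simulated. Nor does a lost call by itself show correlated genes. For cytochrome P450s, the lowest of the 15 lists, the estimated correlation was 0.005, below the preset 0.01. Yet their unadjusted camera p rose from 0.000641 to 0.063. In the other called lists the estimate exceeded the preset. It was 0.66 for neuropeptides, 0.52 for Staphylococcus response genes, 0.37 for heat shock genes and 0.34 for ribosomal proteins, but 0.03 for intestinal proteases. Where genes of a list move together, the preset gives p-values that are too small. The largest median shift of a list was 1.3-fold, and 0 members of any list passed the gene test, adjusted over all genes or adjusted over the list alone. Of the 689 tested members of the 15 lists, 10 had an unadjusted p under 0.05. In 6 of the 15 lists both nisin libraries lay on one side of both controls, where chance alone would give 33.3% of lists. These 15 lists were picked by a test between the groups, which favours such lists. Of the 15, 0 kept their call without each of the 4 libraries in turn.

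Neuropeptide genes, which encode FMRFamide-like, insulin-like and other signalling peptides of neurons, ranked higher with nisin, and 109 of 122 members had a log2 fold change above 0 (median 0.17, camera adjusted p = 1.85e-15). With an estimated correlation, which was 0.66 for this list, the adjusted p was 0.841. Examples that did not pass by themselves were ins-33 (log2 0.60, SE 0.28), nlp-73 (0.47, SE 0.25), nlp-51 (0.45, SE 0.25) and ins-25 (1.39, SE 0.57, from 0.174 to 0.454 CPM). The log2 value of ins-25 was 2.16 without control replicate 2. The list's means overlapped between groups, at -0.27 and 0.08 log2 units from the 4-library mean in the controls and at 0.26 and -0.07 with nisin, as somatic lists did within groups. The call was lost without control replicate 1 (adjusted p = 0.679, median -0.0024) and without nisin replicate 1 (0.528).

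Among genes linked to defence against bacteria, the lysozymes ranked higher with nisin (11 of 13 above 0, median 0.22, camera adjusted p = 4.95e-06; adjusted p = 0.756 with an estimated correlation). So did the list of genes induced by the Gram-positive pathogen Staphylococcus aureus (10 of 13 above 0, median 0.25, adjusted p = 2.09e-07; adjusted p = 0.769 with an estimated correlation), of which 10 also stand in another list. Single members did not pass: the invertebrate-type lysozyme gene ilys-3 had a log2 fold change of 1.2 (SE 0.36; 0.916 to 2.11 CPM), lys-4 had 0.32 (SE 0.18), lys-7 had 0.25 (SE 0.18) and ilys-2 had 0.46 (SE 0.38). The C-type lectin gene clec-61 had 1.15 (SE 0.39; 0.574 to 1.28 CPM), clec-60 had 0.52 (SE 0.35; uncertain, with an overlapping row on its strand), and F53A9.8, annotated with defense response to Gram-positive bacteria, had 0.44 (SE 0.21; 33.0 ± 0.492 to 44.9 ± 0.0646 CPM, SD, n = 2 each). Lysozyme means lay apart in all 4 libraries, and the Staphylococcus response list overlapped. Without control replicate 1 the calls were lost (adjusted p = 0.065 and 0.779), as they were without nisin replicate 1 (0.0647 and 0.319), where the median of the Staphylococcus list was -0.0069.

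Other secreted defence families had smaller medians. C-type lectins (88 of 131 above 0, median 0.07, camera adjusted p = 0.00149), caenopores, which are pore-forming saposin-like proteins (14 of 23 above 0, median 0.09, adjusted p = 0.0183), and antimicrobial peptides of the epidermis (38 of 47 above 0, median 0.14, adjusted p = 0.000691) ranked higher. With an estimated correlation their adjusted p = 0.841, 0.857 and 0.841, in that order. Members with the smallest p, none of which passed, included clec-76 (log2 0.75, SE 0.34), clec-55 (1.305, SE 0.49; uncertain, with an overlapping row on its strand), clec-104 (0.87, SE 0.49), spp-2 (0.46, SE 0.20), spp-8 (0.29, SE 0.20), spp-18 (0.25, SE 0.22), K02A11.4 (0.30, SE 0.27), nlp-33 (0.20, SE 0.15), nlp-28 (0.27, SE 0.23), fip-2 (0.22, SE 0.18) and fip-1 (1.64, SE 0.94). Counts were low for clec-55 and clec-104, at means of 0.576 and 0.408 CPM. The value of fip-1 rests on nisin replicate 1, at 1.14 CPM. Nisin replicate 2 (0.109 CPM) lay below both controls (0.247 and 0.139 CPM). The log2 value of fip-1 was 1.302 without control replicate 2 and 2.52 without nisin replicate 2. Without nisin replicate 1 the filter dropped fip-1 and it had no value. Without control replicate 1 the adjusted p of the 3 lists was 0.679, 0.152 and 0.308, and without nisin replicate 1 it was 0.0647, 0.973 and 0.528. Without control replicate 2 the caenopores (0.0961) and epidermal peptides (0.0718) lost their calls too. The epidermal list's median was -0.03 without nisin replicate 1. That of the C-type lectins was -0.03 without control replicate 1.

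Chitinase-like genes, which respond to oomycetes, had the largest list median (15 of 16 above 0, median 0.38, camera adjusted p = 2.1e-07; adjusted p = 0.756 with an estimated correlation). The named members had low counts. Of these, chil-18, chil-3, chil-6 and chil-17 had log2 fold changes of 0.73 (SE 0.40), 0.61 (SE 0.40), 0.79 (SE 0.52) and 0.64 (SE 0.50) at means of 0.711, 0.680, 0.411 and 0.458 CPM, and the list's call was lost among genes with a mean count of at least 50 (median 0.13, adjusted p = 0.0967) and without control replicate 1 (0.328). The list's means lay apart in all 4 libraries.

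Intestinal proteases, the cathepsin B-like and aspartic proteases, ranked higher with nisin (16 of 19 above 0, median 0.13, camera adjusted p = 3.52e-06; adjusted p = 0.756 with an estimated correlation). All 4 libraries were apart, at -0.13 and -0.01 in the controls and 0.07 and 0.07 with nisin. The abundant members cpr-1 (270 ± 23.6 to 367 ± 64.1 CPM, SD, n = 2 each; log2 0.44, SE 0.18), cpr-4 (195 ± 24.4 to 258 ± 13.2 CPM, SD, n = 2 each; log2 0.40, SE 0.17), cpr-9 (log2 0.18, SE 0.14) and asp-1 (log2 0.18, SE 0.15) did not pass. The call was lost without control replicate 1 (adjusted p = 0.153), where the value of asp-1 was -0.02.

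Ribosomal protein genes had values above 0 in 75 of 77 cases, with a median log2 fold change of 0.06 (camera adjusted p = 9.51e-09; adjusted p = 0.841 with an estimated correlation). Their share of all counts was 15.43% (95% interval 15.417 to 15.439) and 16.21% (16.203 to 16.227) in the controls and 17.01% (17.001 to 17.024) and 16.01% (15.998 to 16.019) with nisin, so the groups overlapped. The median stood at percentile 94.3 of random lists matched on expression, which draw on the same abundant genes. Examples were rpl-39 (log2 0.23, SE 0.11), rpl-41.2 (0.19, SE 0.12), rps-23 (0.14, SE 0.10) and rpl-38 (0.13, SE 0.11), none past the test. The call was lost without control replicate 1 (adjusted p = 0.118) and without nisin replicate 1 (0.0647). Nuclear genes of oxidative phosphorylation (35 of 44 above 0, median 0.06, camera adjusted p = 0.0183; adjusted p = 0.769 with an estimated correlation) included cox-5A (log2 0.12, SE 0.13), atp-5 (0.12, SE 0.14), cox-6A (0.13, SE 0.15) and cyc-2.1 (0.10, SE 0.13). That list's means lay apart in all 4 libraries, and its call was lost without any 1 of them (adjusted p = 0.328 without control replicate 1, 0.184 without control replicate 2, 0.146 without nisin replicate 1 and 0.409 without nisin replicate 2).

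Cytochrome P450 genes, the phase I oxidases, ranked higher with nisin and had 40 of 63 members above 0 (median 0.07, camera adjusted p = 0.00308; adjusted p = 0.756 with an estimated correlation), among them cyp-34A1 (log2 0.67, SE 0.34), cyp-34A5 (0.62, SE 0.33), cyp-34A9 (0.44, SE 0.26) and cyp-13A7 (1.15, SE 0.59). The log2 value of cyp-13A7, at a mean of 0.211 CPM over all libraries, was 1.78 without control replicate 1. The control left there, replicate 2, stood at 0.0833 CPM, the level of 3 counts. Genes raised by the FOXO factor DAF-16 had 15 of 23 above 0 (median 0.07, adjusted p = 0.00323; adjusted p = 0.769 with an estimated correlation), among them the metallothionein gene mtl-1 (log2 0.52, SE 0.22; 42.6 ± 6.63 to 60.95 ± 3.32 CPM, SD, n = 2 each), the linker histone gene hil-1 (0.47, SE 0.27) and the noncoding RNA tts-1 (0.29, SE 0.18). Fatty acid oxidation and lipolysis genes ranked higher (adjusted p = 0.0373; adjusted p = 0.769 with an estimated correlation) with 28 of 51 above 0 and a median of 0.0027, which lay below 0 with DESeq2 size factors and with library totals. Members with the smallest p, none past the test, were acdh-5 (log2 2.37, SE 0.67, at a mean of 0.209 CPM), the lysosomal lipase genes lipl-1 (0.58, SE 0.26) and lipl-3 (0.69, SE 0.34), and ech-9 (0.63, SE 0.37). The values of lipl-3 and ech-9 are uncertain, as each overlaps another row on its strand. Both controls of acdh-5, at 0.0742 and 0.0555 CPM, stood at or below the level of 3 counts. The size of the acdh-5 change is therefore uncertain too. Without control replicate 1 the adjusted p of the 3 lists was 0.113, 0.328 and 0.679, and without nisin replicate 1 it was 0.0647, 0.385 and 0.0647. The P450 (0.184) and fatty acid oxidation (0.0961) calls were lost without control replicate 2 as well, and the latter also without nisin replicate 2 (0.468) and among genes with a mean count of at least 50 (0.122).

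Heat shock genes, the chaperones controlled by HSF-1, ranked lower with nisin, and 19 of 21 members had a log2 fold change below 0 (median -0.18, camera adjusted p = 9.51e-09; adjusted p = 0.769 with an estimated correlation). Mean counts were 524 ± 116 CPM in the controls and 368 ± 81.2 CPM with nisin for hsp-16.41 (SD, n = 2 each), 347 ± 68.03 and 250 ± 61.4 CPM for hsp-16.2 (SD, n = 2 each), and 82.1 ± 15.1 and 57.8 ± 11.5 CPM for hsp-70 (SD, n = 2 each). The value of hsp-16.48 (log2 -0.61, SE 0.29) is uncertain because hsp-16.49 is a near-identical copy. The list's means were -0.04 and 0.24 in the controls and 0.06 and -0.26 with nisin, and so overlapped. Its median gaps from replicate 1 to 2, 0.32 in the controls and -0.41 with nisin, had the signs of the somatic lists. Both gaps lay outside the middle 95% of matched random lists. The call was lost without control replicate 2 (adjusted p = 0.186) and without nisin replicate 2 (0.172). Genes switched on in the embryo, a list that followed the germline genes within groups, ranked higher. Members included sdz-12 (log2 0.98, SE 0.54, at a mean of 0.254 CPM), sdz-18 (0.37, SE 0.36), tbx-37 (0.31, SE 0.38) and sdz-26 (0.27, SE 0.34). Of this list 23 of 39 were above 0 (median 0.08, camera adjusted p = 0.0401, or 0.938 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.0502, median -0.18) and without nisin replicate 2 (0.953, median -0.04).

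**Figure D3:**
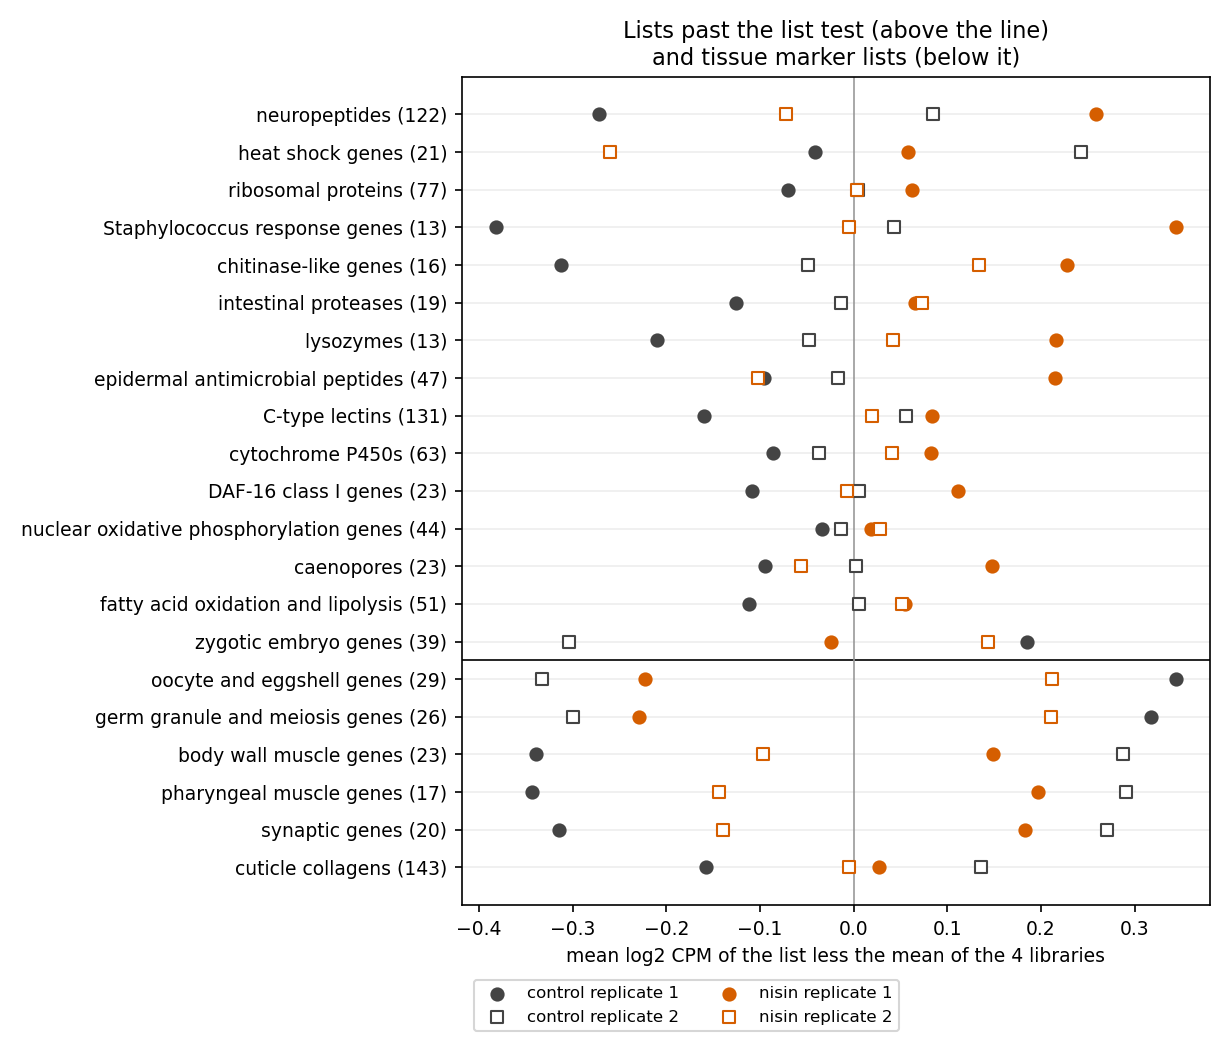
Mean log2 CPM of each list in each library, less the mean of the 4 libraries, for the 15 lists past the camera test above the line and 6 tissue marker lists below it, with tested members in parentheses; grey is control, orange is nisin, filled circles are replicate 1 and open squares replicate 2. Intestinal proteases lie at -0.13 and -0.01 in the controls and at 0.07 and 0.07 with nisin, while oocyte and eggshell genes lie at 0.34 and -0.33 in the controls and at -0.22 and 0.21 with nisin.

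The other 33 lists did not pass (smallest adjusted p = 0.0709). Immune lists among them had medians near 0, with -0.0092 over 17 PMK-1 immune targets (camera adjusted p = 0.893), 0.04 over 9 ZIP-2 and infection response genes (0.51), 0.01 over 43 genes of the intracellular pathogen response (0.826) and -0.01 over 314 F-box and MATH genes (0.895). Stress lists gave 0.01 for SKN-1 targets (0.826), -0.0036 for mitochondrial stress response genes (0.805), -0.03 for endoplasmic reticulum stress genes (0.521), -0.09 for hypoxia response genes (0.218), 0.06 for metal response genes (0.0882), -0.05 for autophagy genes (0.323) and -0.02 for genes lowered by DAF-16 (0.447). Detoxification lists gave 0.02 for glutathione S-transferases (0.0918), -0.04 for UDP-glucuronosyltransferases (0.447) and 0.0061 for ABC transporters (0.826).

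Metabolic lists that did not pass were glycolysis and gluconeogenesis (median 0.04, camera adjusted p = 0.0882), fatty acid synthesis and desaturation (0.04, 0.12), the propionate shunt (-0.03, 0.511), the methionine and SAM cycle (-0.0091, 0.889), the vacuolar ATPase (0.03, 0.218), the proteasome (0.02, 0.648) and aminoacyl-tRNA synthetases (-0.02, 0.304). Vitellogenins had a median of -0.08 over 6 genes (0.0882), some of which are near-identical copies. Tissue and stage lists gave histones (0.01, 0.0709), body wall muscle (0.03, 0.0789), pharyngeal muscle (-0.0049, 0.238), synaptic genes (0.02, 0.389), moulting genes (-0.07, 0.424), cuticle collagens (0.02, 0.447), germ granule and meiosis genes (-0.05, 0.501), oocyte and eggshell genes (-0.03, 0.521) and sperm genes (0.0051, 0.799). Transthyretin-like genes had 0.02 (0.447) and nuclear hormone receptors 0.01 (0.826). In 7 of the 48 lists, pharyngeal muscle, cuticle collagens, genes lowered by DAF-16, intracellular pathogen response, methionine and SAM cycle, PMK-1 targets and F-box and MATH genes, the median, the mean and the test did not share one sign.

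Single genes fixed beforehand as reporters of known responses did not pass either (edgeR adjusted p = 1 for each). The PMK-1 target T24B8.5, named sysm-1 in the tables, had a log2 fold change of -0.13 (SE 0.34), and the infection response genes irg-1, irg-4 and irg-5 had 0.23 (SE 0.30), 0.06 (SE 0.26) and 0.08 (SE 0.37). The superoxide dismutase gene sod-3 had 0.14 (SE 0.29). The SKN-1 reporter gst-4 had -0.19 (SE 0.26), which is uncertain, with an overlapping row on its strand. The chaperone genes hsp-6 of the mitochondrial and hsp-4 of the endoplasmic reticulum stress response had -0.03 (SE 0.14) and -0.06 (SE 0.14), with 95% intervals of -0.35 to 0.28 and -0.38 to 0.26. The yolk protein gene vit-2 had -0.10 (SE 0.16), the desaturase gene fat-7 had 0.32 (SE 0.27), the propionate shunt gene acdh-1 had -0.03 (SE 0.13) and the flavin monooxygenase gene fmo-2 had 0.31 (SE 0.35). The values of sysm-1, irg-1, irg-4, irg-5, sod-3, gst-4, hsp-6, vit-2, acdh-1 and fmo-2 changed sign without at least 1 of the 4 libraries.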

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

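The alternatives given here were set beforehand, except the crossed pairing, a test chosen only after the correlation of same-numbered libraries was seen; the rule that a list's direction is that of its test was settled after other rules had been tried, and the standard error behind the intervals was replaced after both kinds had been seen. Over 76 named genes, 747 values from other scalings, filters, tests and the replicate block kept their direction and their side of the threshold. Just 1 value did not, that of T22F3.11 with DESeq2 (log2 2.05, adjusted p = 2.82e-05). The crossed pairing was not among these values. The count of genes higher was 0 in edgeR (65 genes at an unadjusted p under 0.05) and in limma-voom, and 1 with DESeq2. The genes-lower count was 0 by all 3 tools.

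Which library was left out mattered more than the scaling. Without 1 library, 0 to 4 genes were called higher and 0 to 2 lower. The 4 higher genes without control replicate 1 were T22F3.11, pud-3, pud-4 and drd-10, and the 3 without control replicate 2 were T22F3.11, F46C5.1 and C17F4.12; the lower ones were ZK180.5 and cut-2 without control replicate 1 and scl-12 and F57F4.2 without control replicate 2. These genes, except T22F3.11 and F46C5.1, were chosen after their values were seen. Where a library was left out, the lone library of that group was assumed to vary like the other group. The lists called higher ranged from 7 (without control replicate 1) to 16 (without control replicate 2), with 8 without nisin replicate 1, and those called lower from 2 (without nisin replicate 1) to 9 (without control replicate 1), against 14 and 1 with all 4 libraries. Lists that differed within groups followed the library left out, since the opposite gaps of the 2 groups then no longer offset each other. Without control replicates 1 and 2 and nisin replicates 1 and 2, oocyte and eggshell genes had medians of 0.36, -0.34, 0.16 and -0.27. Body wall muscle genes had -0.23, 0.39, -0.06 and 0.13 in that order. With an estimated correlation 0 lists were called higher and 0 lower, and with fry also 0 and 0. Other causes were not tested.

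The libraries share only a replicate number: the deviations of same-numbered libraries from their group means correlated at -0.601 across genes. With the replicate block 0 genes were called, 12 lists were higher and 2 lower; caenopores (adjusted p = 0.063) and oxidative phosphorylation genes (0.0744) were not called and vitellogenins were called lower (0.0152). With the crossed replicate block, which pairs the libraries that were most alike and so lowers the spread left over, 10 genes were called higher and 2 lower, and 15 lists higher and 2 lower.

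Among genes with a mean count of at least 50, chitinase-like genes (adjusted p = 0.0967) and fatty acid oxidation genes (0.122) were not called, and body wall muscle genes (0.0322) and fatty acid synthesis genes (0.0258) were. In the same setting the direction of the test turned for 4 lists, with medians of -0.043 for DAF-16 class II genes, -0.018 for F-box and MATH genes, 0.028 for the intracellular pathogen response and 0.0017 for nuclear hormone receptors. With fry it turned for PMK-1 immune targets (median -0.0092). None of these 5 lists with a turned direction was called in either setting, and the cause was not tested.

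Without nisin replicate 1 the filter dropped fip-1, so its direction there was not counted. Without 1 library in turn, the direction turned for 13 of the 76 genes. Their lowest and highest log2 fold changes were asp-1 (-0.021 to 0.41), tbx-37 (-0.032 to 0.80), sdz-26 (-0.015 to 0.65), sysm-1 (-0.57 to 0.52), irg-1 (-0.044 to 0.46), irg-4 (-0.095 to 0.24), irg-5 (-0.28 to 0.58), sod-3 (-0.038 to 0.29), gst-4 (-0.43 to 0.040), hsp-6 (-0.079 to 0.018), vit-2 (-0.37 to 0.13), acdh-1 (-0.12 to 0.061) and fmo-2 (-0.074 to 0.61). It turned for 29 of the 48 lists, of which 2 were called with all libraries, epidermal antimicrobial peptides and zygotic embryo genes. Lowest and highest medians were ABC transporters (-0.093 to 0.23), aminoacyl-tRNA synthetases (-0.13 to 0.071), body wall muscle genes (-0.23 to 0.39), cuticle collagens (-0.19 to 0.29), DAF-16 class II genes (-0.087 to 0.13), epidermal antimicrobial peptides (-0.027 to 0.22), ER stress response genes (-0.034 to 0.015), F-box and MATH genes (-0.18 to 0.21), germ granule and meiosis genes (-0.30 to 0.33), glutathione S-transferases (-0.035 to 0.19), histones (-0.051 to 0.32), hypoxia response genes (-0.25 to 0.11), intracellular pathogen response (-0.19 to 0.22), methionine and SAM cycle (-0.052 to 0.068), mitochondrial stress response genes (-0.050 to 0.038), moulting genes (-0.26 to 0.19), nuclear hormone receptors (-0.17 to 0.21), oocyte and eggshell genes (-0.34 to 0.36), pharyngeal muscle genes (-0.35 to 0.37), PMK-1 immune targets (-0.057 to 0.047), propionate shunt (-0.17 to 0.12), proteasome (-0.17 to 0.25), SKN-1 targets (-0.015 to 0.022), sperm genes (-0.068 to 0.095), synaptic genes (-0.26 to 0.42), vacuolar ATPase (-0.080 to 0.20), vitellogenins (-0.31 to 0.15), ZIP-2 and infection response genes (0.0045 to 0.16) and zygotic embryo genes (-0.18 to 0.50). A median can keep its sign where the test turned, and a median can turn where the test did not. Among lists called with all libraries that held for neuropeptides (-0.0024) and C-type lectins (-0.027) without control replicate 1 and for the Staphylococcus response genes (-0.0069) without nisin replicate 1. Of genes with a mean of at least 5 CPM, 97.9% had an interval within 2-fold, whose width holds both counting error and spread between libraries; in the simulation 38.8% of 2-fold changes were recovered. The alternative that leaves out mitochondrial and ribosomal RNA genes was not run, since there were 0 such genes.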

Other observations

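The tests of gene ontology terms, of germline and somatic shares, of exchanged labels, of other splits and of the share of neuronal RNA were chosen only after the result was seen. The intestinal structure genes were not one of the lists fixed before the data were examined. They were compared with lists already seen to rank higher, under a bound written before that comparison's values were seen.

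Genes of sensory cilia, a group not covered by the lists above, ranked lower in the nisin libraries. Of 28 genes of the ciliary transition zone, the gate at the base of the cilium, 3 had a log2 fold change above 0 (median -0.26, camera adjusted p = 0.000483 over 1157 terms), and 0 of 10 genes that localize proteins to it did (median -0.3, adjusted p = 0.00294). Each of these 2 terms, and each of the 3 on cilia and cell projections that follow, had an adjusted p = 1 with an estimated correlation. Non-motile cilium assembly (36 genes, median -0.21, adjusted p = 0.000976), cilium assembly (54 genes, median -0.099, 0.0498) and cell projection organization (30 genes, median -0.12, 0.0488) also ranked lower. Library means of each of these cilium and projection terms overlapped between groups. For the transition zone they were -0.21 and 0.39 in the controls and 0.13 and -0.31 with nisin. Non-motile cilium assembly had -0.22 and 0.38 in the controls and 0.12 and -0.28 with nisin. From replicate 1 to 2 the means of each term rose in the controls and fell with nisin, as those of muscle and synaptic genes did. How many genes the terms share was not counted. Unfolded protein binding was also lower (52 genes, median -0.05, adjusted p = 0.000447), with its means apart in all 4 libraries; its adjusted p = 1 with an estimated correlation.

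Terms that ranked higher were neuropeptide signaling (138 genes, median 0.16, camera adjusted p = 3.83e-11), hormone activity (21 genes, 0.12, 0.0049), the large (46 genes, 0.06, 0.000447) and small (33 genes, 0.06, 0.0107) cytosolic ribosomal subunits and defense response to Gram-positive bacteria (68 genes, 41 above 0, median 0.03, 0.0049). Library means overlapped for neuropeptide signaling (-0.29 and 0.13 in the controls, 0.24 and -0.08 with nisin). They also did for hormone activity (-0.22 and -0.01 in the controls, 0.26 and -0.03 with nisin). The means lay apart, by little, for both ribosomal subunits and for defense response to Gram-positive bacteria. Control replicate 2 and nisin replicate 2 stood at 0.0007 and 0.0047 for the defense term, and at 0.0059 and 0.0134 for the large subunit. For the small subunit, control replicate 1 stood at -0.0018 and nisin replicate 2 at 0.0114. In all, 5 terms were higher and 6 lower with the preset correlation. With an estimated correlation 0 passed (smallest adjusted p = 1). In the simulation, whose genes were drawn independently, an estimated correlation recovered 0 of 5 shifted lists. The lost calls thus do not by themselves argue against a shift of these terms. How often the preset correlation calls unshifted terms whose genes move together was not simulated, so the preset calls do not establish a shift either. Leaving out libraries was not tried for these terms.

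The 2 controls correlated less (0.9817) than any 2 libraries of different groups (0.9866 to 0.9944), while the 2 nisin libraries (0.9911) stood between these, and gaps between replicates lay outside matched random lists in both groups with opposite signs, germline one way and somatic the other, in 9 of 11 marker lists; sperm genes and intestinal proteases were the exceptions. Different germline shares are thus a candidate explanation. Vitellogenins, made in the intestine and not among the 11 lists, also had gaps of the germline signs (medians -0.39 between controls and 0.39 between nisin libraries). The split was therefore not simply germline against somatic genes, and why shares would differ was not tested. Depth and gene length are argued against, since the gaps of the 2 groups still correlated at -0.583 across genes after thinning to one depth and at -0.606 after removing a trend on length. Whether 1 library of each group carries the other's label stays open: with the crossed pairs as a block the labelled groups separated 12 genes and the replicate numbers 3, and the deposited tables number the libraries of both groups 2 and 3 where the labels have 1 and 2, which by itself moves no library between groups. Of the 3 splits of the 4 libraries, too few for a share under 0.05, the labelled one separated 0 genes and the highest other 6385, along the pairs that correlate best, so that count restates their correlation.

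Neuropeptide genes ranked higher with nisin with the preset correlation (adjusted p = 0.841 with an estimated correlation), with overlapping library means and a median of -0.0024 without control replicate 1. Low expression of the list is argued against, as its median stood at percentile 100 of 10000 matched random lists. A larger share of neuronal RNA could raise them; synaptic genes had a median of 0.02 against 0.17 (two-sided permutation p = 0.00027 across genes, not independent replicates). This p does not decide, because genes of a list move together: the difference between the 2 lists was 0.143 between groups but up to 0.227 between libraries of one group, a requirement added after the values were seen. A response to nisin, the difference the design names, also stays open and was not tested apart from these.

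Intestinal protease and lysozyme genes ranked higher with nisin with the preset correlation (adjusted p = 0.756 for both with an estimated correlation, and 0.153 and 0.065 without control replicate 1), and a larger share of intestinal RNA could do this. Against 15 intestinal structure genes (median 0.0068), the 32 protease and lysozyme genes had a median of 0.14 (permutation p = 0.0039 across genes). This met the bound, written before that comparison's values were seen, for excluding that explanation. Both lists had been picked because they ranked higher in these data, which favours such a difference. The bound was wrong for these data, as the difference between the lists was 0.161 between groups and up to 0.382 between libraries of one group; this was required only after the values were seen. The explanations cannot be told apart with 2 libraries per group, and a response to nisin stays open, untested apart from them.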
